A study of Homo sapiens with 11 samples.

How the data were processed

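The series holds 11 chromatin immunoprecipitation sequencing (ChIP-seq) libraries in 8 groups. In primary human bronchial epithelial (HBE) cells, 2 libraries were made with an antibody against EHF, an ETS-family transcription factor of epithelia, with 1 library for each of 3 histone marks and 1 input library. In Calu-3, a human lung adenocarcinoma cell line, 2 libraries were made against c-Jun and 2 against JunD, both members of the AP-1 transcription factor family, with 1 input library. Per the labels' protocols, nuclei were lysed and sonicated, the libraries were size-selected and amplified, and sequencing was done on an Illumina HiSeq. The labels name the input of the same cells as the control for peak calling.

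Only peak lists were analysed. There are 3, for EHF, c-Jun and JunD, and each holds the joint peaks of 2 replicates, named in the labels after the irreproducible discovery rate (IDR), a measure of how well replicates rank the same peaks. Values of single replicates, the input libraries and the histone mark libraries are not analysed here. The submitters' processing notes name Bowtie 1.0.0, HOMER 1.2 and the genome build hg19, and the file headers carry HOMER findPeaks column names. The IDR threshold and the peak calling threshold are not given in the sources used here. The authors deposited 1 whole-number score per peak, which falls from the top to the bottom of each list. The headers give 15 column names over 6 data columns, so they do not say which HOMER quantity the deposited score is. It was used to rank, describe or select peaks within 1 list. Log2 scores also entered correlations over regions shared by c-Jun and JunD and over autosomes. Scores of different lists have no known common scale. Every peak of a list has the same width, and no 2 peaks of a list overlap. The peak names carry a running number per chromosome. The highest of these numbers, summed over chromosomes, came to 25975 for EHF, 18243 for c-Jun and 10433 for JunD, so that the lists hold at most 43.6%, 63.1% and 72.1% of the numbered peaks. Read depth is unknown, so no limit of detection could be set, and a region missing from a list is a region that was not called.

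Positions are given on hg19, counted from 1, with the start of each BED line raised by 1 base. The peaks overlapped when they shared at least 1 bp. Chance was estimated by moving every peak of the first list by a random distance of 10 to 100 kb in either direction, in 1000 draws. Such moves keep the regional density of peaks along the chromosome, but not their clustering over shorter distances. The fold over chance is the observed number over the mean of the draws. Its p-value is a two-sided permutation p, and 0.001 is the smallest that 1000 draws can give. The 95% intervals of folds, and the standard errors of shares marked as such, come from leaving out each chromosome in turn (jackknife). Other intervals of shares are exact binomial (Clopper-Pearson) 95% intervals. Classes of peaks were compared by Fisher's exact test, two-sided, with the odds ratio and its Woolf 95% interval, and pooled over score strata by the Mantel-Haenszel method. Regions are the counted unit in all these tests. The p-values and intervals therefore describe the placement of called regions and do not measure the spread between replicates or cultures. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

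The overlap test was tested on simulated lists. For an EHF-like list of 11326 peaks against the c-Jun list with 9.99% of peaks planted on c-Jun peaks, the measured share was 10.1%. With nothing planted, 1 of 40 simulated lists had a p below 0.05. These unplanted lists were made by moving the EHF peaks by 500 to 1000 kb, and their median fold was 0.993. The test was first made with lists moved by 10 to 100 kb, the distances the test itself uses. Of 40 such lists 6 had a p below 0.05, all 6 with a fold below 1, and the median fold was 0.812. The longer distance was chosen after that result, and the cause of the low folds was not tested. For a c-Jun-like list of 11517 peaks against the JunD list with 9.99% planted, the measured share was 10.1%. With nothing planted, 1 such list moved by 500 to 1000 kb had a fold of 0.682. All simulations used fewer than 1000 draws.

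The overlaps with their permutation tests, the comparison of peak classes by Fisher's exact test, the alternatives listed next for the overlaps and the rule for named regions were fixed before the data were examined. The rule takes the 10 best-scored peaks and the 10 densest 100 kb regions of each list, by position, because no annotation of hg19 was used here. For the same reason the planned analyses of promoters, of 26 sequence patterns and of 19 gene lists were not run, and no gene is assigned to a peak. The alternatives for the overlaps were the better-scored 50% of each list, peaks set to 200 bp, autosomes only, an overlap of at least 50% of the shorter peak, midpoints within 100 bp, and random placement on the same chromosome. All else was added after seeing the data: the 5 equal groups by score, the distances between peaks, the relation of scores over shared regions, the count of neighbours of the 10 best peaks, the autosomes and 1 Mb windows with their correlations, and the stretch of chromosome 17. The score strata, the lists without the top 5% of peaks and the count of peaks within 1 kb as 1 locus were also chosen after seeing the data. Comparisons by chromosome were limited to the 22 autosomes. Fisher's exact tests over autosomes or windows were adjusted by the Benjamini-Hochberg method within each pair of lists, at a threshold of 0.05.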

Results

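The binding of EHF was mapped in primary human bronchial epithelial cells, and that of c-Jun and JunD in Calu-3 lung adenocarcinoma cells, each from 2 replicates joined into 1 list of reproducible peaks. The EHF list held 11326 peaks of 195 bp, which together cover 2209 kb of the genome. The c-Jun list held 11517 peaks of 123 bp and the JunD list 7524 peaks of 133 bp. The authors' score, a whole number per peak, had a median of 10 in the EHF list with quartiles of 9 and 14, and ranged from 8 to 839. It had a median of 7 for c-Jun, with quartiles of 6 and 10 and a range of 5 to 275. For JunD the median was 11, the quartiles were 9 and 14 and the range was 7 to 376. The lowest score was held by 20.9% of EHF peaks, 20.5% of c-Jun peaks and 4.33% of JunD peaks. No list has values per replicate, and no error between replicates could be given.

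The best-scored EHF regions were a pair of neighbouring peaks on chromosome 1. They lie at positions 59247834 to 59248028, with a score of 839, and 59248404 to 59248598, with a score of 818. The next EHF peak, at 9827342 to 9827536 on chromosome 21, scored 350. Both Jun lists also held a pair of peaks within 1 kb of these chromosome 1 peaks. The c-Jun pair lay at 59247948 to 59248070 and 59248268 to 59248390, with scores of 88 and 90, which rank among the 10 best of that list. The best JunD peak there, at 59247963 to 59248095, scored 75 and was the ninth of its list. Regions on chromosome 21 between 9825454 and 9827536 were likewise among the 10 best in all 3 lists. The EHF peak at 9825454 to 9825648 scored 294, the c-Jun peak at 9825526 to 9825648 scored 99, and the JunD peak at 9826011 to 9826143 scored 93. Whether the best-scored regions of a list are binding sites or are found with any antibody was not tested.

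Other EHF peaks among the 10 best had no Jun peak within 1 kb. These were the peaks at 33478077 to 33478271 on chromosome 17 (score 329), 85195005 to 85195199 on chromosome 11 (316), 20704322 to 20704516 on chromosome 12 (145) and 33963827 to 33964021 on chromosome 16 (118). Of the 10 best EHF peaks, 6 lay within 1 kb of a c-Jun or JunD peak, against 1701 of the 11316 other EHF peaks. Of the 10 best JunD peaks, 7 lay within 1 kb of an EHF peak, against 1130 of the 7514 other JunD peaks. Fisher's exact tests of these counts gave p = 0.00141 for EHF and p = 0.000139 for JunD, without adjustment. They count as independent several best peaks that are close neighbours on chromosomes 1 and 21, so these p-values are too small. They were also the smallest of several such tests. Of the 10 best c-Jun peaks, 5 lay within 1 kb of an EHF peak (Fisher's exact p = 0.00675). Within 1 kb of either other list lay 9 of the 10 best c-Jun peaks and all 10 best JunD peaks (Fisher's exact p = 0.0583 and 0.381). A c-Jun peak was as near to 8 of the 10 best JunD peaks, against 81.6% of the others.

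**Figure D1:**
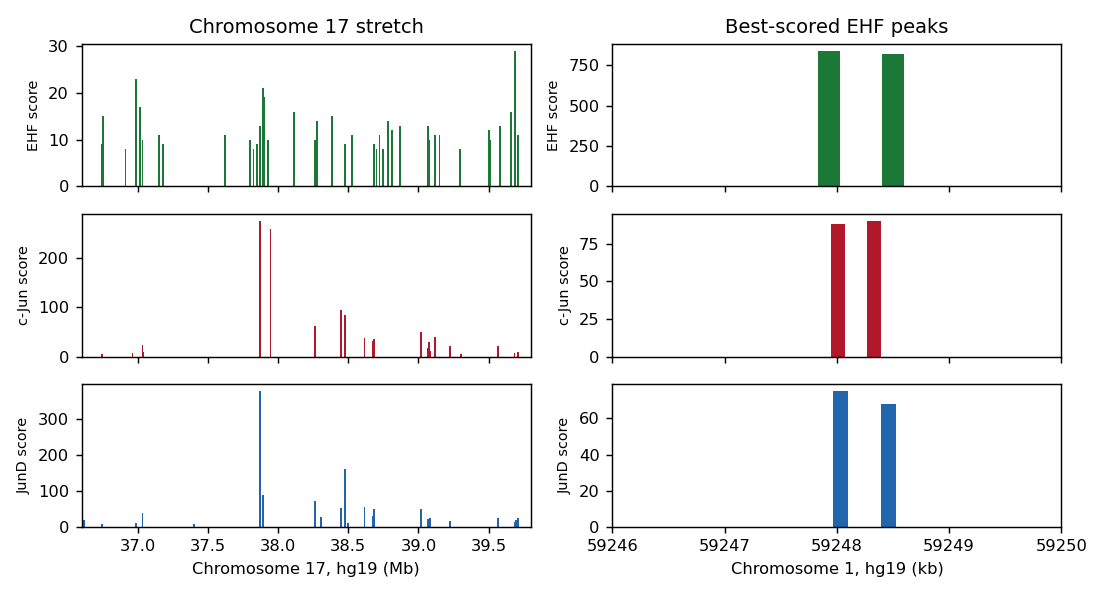
Authors' peak score (bar height) against position on hg19 for EHF in HBE cells and for c-Jun and JunD in Calu-3 cells, on chromosome 17 (left, Mb) and chromosome 1 (right, kb), with a separate linear score axis per panel and bars on the left drawn wider than the peaks. On chromosome 1 each list has a pair of peaks within 1 kb. Within 37862148 to 38471117 on chromosome 17 the c-Jun and JunD scores reach 275 and 376, and no EHF peak exceeds 21. Scores of different lists have no known common scale.

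In Calu-3 cells many of the best-scored c-Jun and JunD peaks gathered on chromosome 17. Within 37862148 to 38471117, a stretch of 609 kb, lay 5 of the 10 best c-Jun peaks and 4 of the 10 best JunD peaks. The best peak of each Jun list was at its start, at 37862158 to 37862280 for c-Jun (score 275) and 37862148 to 37862280 for JunD (score 376). A c-Jun peak at 37938825 to 37938947 scored 258 and had no JunD peak within 1 kb. The region at 38470985 to 38471117 held the second JunD peak, with a score of 160, beside a c-Jun peak at 38470991 to 38471113 with a score of 84. All 7 c-Jun peaks of the stretch scored 36 or more, against a list median of 7, and all 8 JunD peaks scored 26 or more, against a list median of 11. The 10 EHF peaks of the same stretch scored 9 to 21, with a median of 13.5, against a list median of 10. The stretch was chosen after its values were seen. Extra DNA copies in Calu-3 cells and a cluster of strong Jun sites could not be told apart there.

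The comparison of c-Jun with JunD asks how far these AP-1 proteins occupy the same sites in the same cells. Most JunD sites were also c-Jun sites. Of the 7524 JunD peaks, 6052 overlapped a c-Jun peak, or 80.4% (exact 95% interval 79.5% to 81.3%, jackknife SE 0.737 percentage points). Of the 11517 c-Jun peaks, 6052 overlapped a JunD peak, or 52.5% (51.6% to 53.5%, jackknife SE 1.54). That left 5465 c-Jun peaks and 1472 JunD peaks without a partner. Moved c-Jun peaks met a JunD peak 19.7 times on average (SD 4.55 over 1000 draws), so the observed overlap was 307-fold over chance (281 to 336, permutation p = 0.001). Midpoints of overlapping c-Jun and JunD peaks were a median of 13 bp apart. Both lists were called against the same Calu-3 input library, which can add shared regions. The fold ranged from 197 with all peaks set to 200 bp to 720 with peaks placed at random on their chromosome.

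The c-Jun sites without a JunD peak were mostly the weaker ones. When c-Jun peaks were ordered by score and divided into 5 equal groups, 87.8% of the best group overlapped a JunD peak (exact 95% interval 86.4% to 89.2%), against 20.6% in the last group (18.9% to 22.3%). For JunD the shares were 93.8% in the best group and 64.5% in the last (odds ratio 8.36, 95% interval 6.61 to 10.6, Fisher's exact p = 3.06e-94). Across the 6052 shared regions the log2 scores of c-Jun and JunD rose together, with a Pearson r of 0.69 and a Spearman rho of 0.61 (permutation p = 1e-05 for each, the smallest that 100000 resamples can give). Without the 2 regions of highest c-Jun score r was 0.68. This is a relation across regions, which are not independent replicates.

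**Figure D2:**
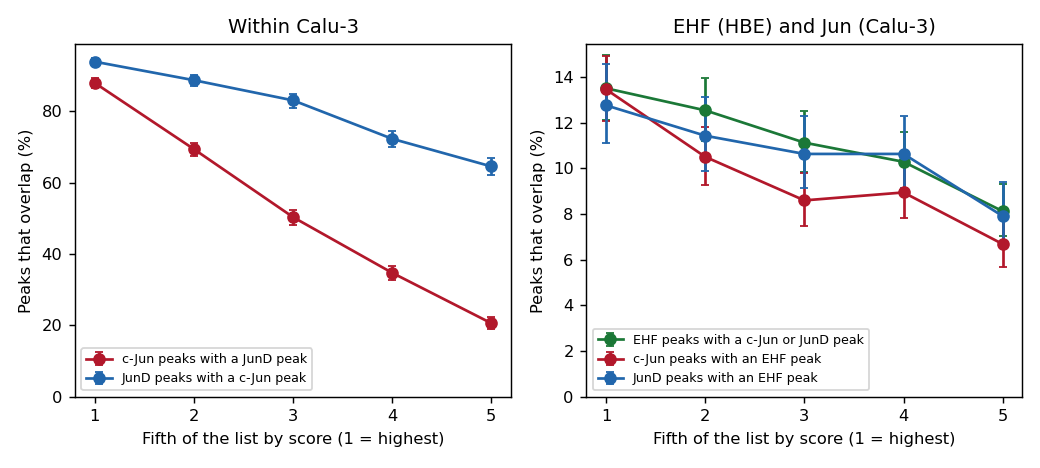
Share of peaks that overlap a peak of another list (y axis, %, from 0) in 5 equal groups of the list ordered by the authors' score (x axis, 1 is highest), with exact 95% binomial intervals as bars. The c-Jun overlap with JunD falls from 87.8% to 20.6% and the EHF overlap with either Jun list from 13.5% to 8.12%.

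The comparison of EHF with c-Jun and JunD asks whether EHF sites of bronchial epithelium are also AP-1 sites. Factor and cell type differ together here, since EHF was mapped in HBE cells and the Jun proteins in Calu-3 cells, so the comparison is of places in the genome. Most EHF sites were not Jun sites, but far more coincided with one than chance placement gave. Of the 11326 EHF peaks, 1259 overlapped a c-Jun or JunD peak, or 11.1% (exact 95% interval 10.5% to 11.7%, jackknife SE 0.606). Of these, 654 overlapped both, 456 overlapped c-Jun alone and 149 overlapped JunD alone. The other 10067 EHF peaks, or 88.9%, overlapped neither. Moved EHF peaks met a Jun peak 31.6 times on average (SD 5.57), and no draw exceeded 49, so the overlap was 39.8-fold over chance (37.3 to 42.6, permutation p = 0.001). Taken alone, c-Jun met 1110 EHF peaks, 41.7-fold over chance (38.8 to 44.8), and JunD met 803, 40.8-fold over chance (37.1 to 44.8), each with a permutation p of 0.001. Random placement on the chromosome gave 72.6-fold for both Jun lists together. Midpoints of overlapping EHF and c-Jun peaks were a median of 43 bp apart.

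**Figure D3:**
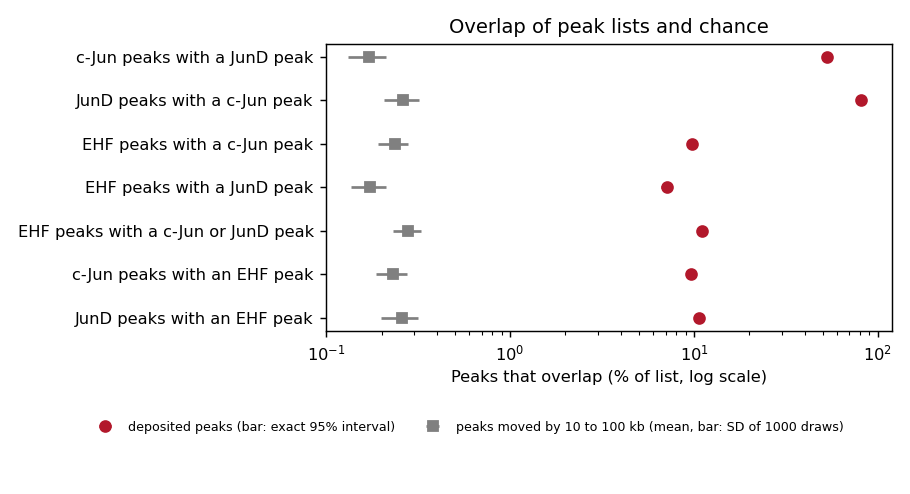
Share of each list's peaks that overlap a peak of another list (x axis, % on a log scale), for the deposited peaks (circles, exact 95% intervals, mostly smaller than the symbols) and for peaks moved by 10 to 100 kb (squares, mean and SD of 1000 draws). The overlap of c-Jun with JunD reaches 52.5% and 80.4%, and the overlaps with EHF lie between 7.09% and 11.1%, all far right of chance.

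Stronger EHF sites were more often Jun sites. In the best of 5 equal groups of EHF peaks by score, 13.5% overlapped a Jun peak, and in the last group 8.12% did (odds ratio 1.77, 95% interval 1.46 to 2.14, Fisher's exact p = 6.09e-09). The same order was seen from the side of c-Jun, with 13.5% of the best group and 6.69% of the last group on an EHF peak (Fisher's exact p = 1.96e-14). For JunD these shares were 12.8% and 7.91% (Fisher's exact p = 1.5e-05). EHF and Jun peaks were also paired beyond chance at distances without overlap. Such a pair can hold a peak that overlaps another peak of the other list, so the excess need not mean separate neighbouring sites. Pairs of EHF and c-Jun peaks with midpoints 200 to 500 bp apart numbered 211, 4.19-fold over chance. At 500 to 1000 bp there were 253 pairs, 3.01-fold over chance, and at 5000 to 10000 bp the excess was 1.29-fold (permutation p = 0.001 in each distance class). EHF and JunD pairs at 200 to 500 bp numbered 159, 4.44-fold over chance.

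**Figure D4:**
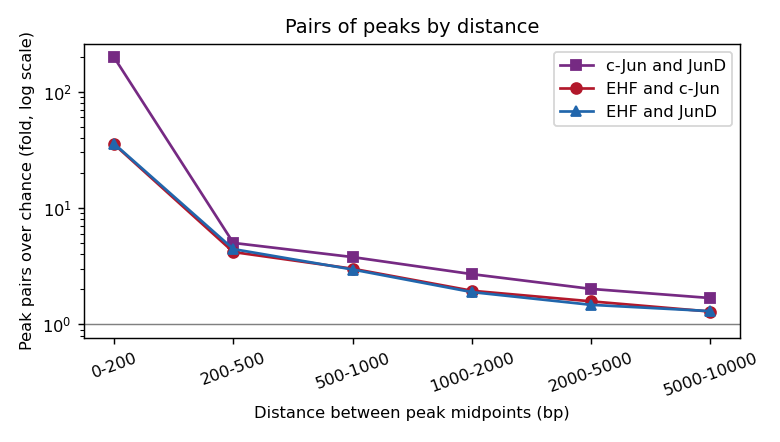
Number of peak pairs over the mean of 1000 draws of moved peaks (y axis, fold on a log scale, grey line at 1) by distance between midpoints (x axis, bp), for c-Jun with JunD and for EHF with each Jun list. The c-Jun and JunD pairs start at 197-fold under 200 bp, the EHF pairs at 35.3-fold and 35.7-fold, and all stay above 1 up to 10000 bp.

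Regions bound by both Jun proteins coincided with EHF more often than regions of c-Jun alone. Of the 6052 c-Jun peaks shared with JunD, 660 overlapped an EHF peak, or 10.9%, against 450 of 5465 c-Jun-only peaks, or 8.23% (odds ratio 1.36, 95% interval 1.20 to 1.55, Fisher's exact p = 1.27e-06). The shared peaks had a median score of 9 and the c-Jun-only peaks of 6, and with score strata held fixed the odds ratio was 1.11 (0.960 to 1.28), which no longer excludes 1. In the JunD list 666 of 6052 shared peaks and 137 of 1472 JunD-only peaks overlapped an EHF peak, a difference that did not pass the threshold (odds ratio 1.20, Woolf interval 0.993 to 1.46, jackknife interval over chromosomes 1.01 to 1.44, Fisher's exact p = 0.0598). With score strata held fixed the odds ratio was 1.07 (0.875 to 1.31). The difference passed in the better-scored 50% of the lists, with an odds ratio of 1.53, and with peaks set to 200 bp, with 1.26, and in none of the other 6 alternatives.

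The EHF peaks of HBE cells and the Jun peaks of Calu-3 cells were spread differently over the autosomes. Factor, cell type and DNA copy number cannot be told apart in this comparison. The share of c-Jun peaks differed from that of EHF peaks on 17 of 22 autosomes, higher on 6 and lower on 11, and the share of JunD peaks differed on 18, higher on 6 and lower on 12 (Fisher's exact test, adjusted p under the threshold). Chromosome 3 held 10.4% of autosomal c-Jun peaks and 12.2% of JunD peaks against 6.64% of EHF peaks (odds ratios 1.63 and 1.95, Fisher's exact test, adjusted p = 9.93e-23 and 9.32e-37). Chromosomes 5 and 7 were also richer in Jun peaks, with c-Jun odds ratios of 1.59 and 1.57 and JunD odds ratios of 1.49 and 1.61. Chromosome 13 held 2.21% of EHF peaks but 0.925% of c-Jun and 0.689% of JunD peaks (odds ratios 0.413 and 0.309). Chromosome 19 held 4.48% of EHF peaks, 2.68% of c-Jun peaks and 3.15% of JunD peaks (odds ratios 0.586 and 0.693). These comparisons were added after the lists had been seen. Both use the same EHF list, and the Jun lists share most of their strong peaks, so they are not independent. Between c-Jun and JunD, 2 autosomes differed by Fisher's exact test. The 6052 shared regions count in both lists, which the test treats as independent, so it can miss differences. Chromosome 3 held a lower share of c-Jun peaks than of JunD peaks (odds ratio 0.835, Fisher's exact test, adjusted p = 0.00153), and chromosome 4 a higher one, 3.32% against 2.23% (Fisher's exact test, adjusted p = 0.000248).

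**Figure D5:**
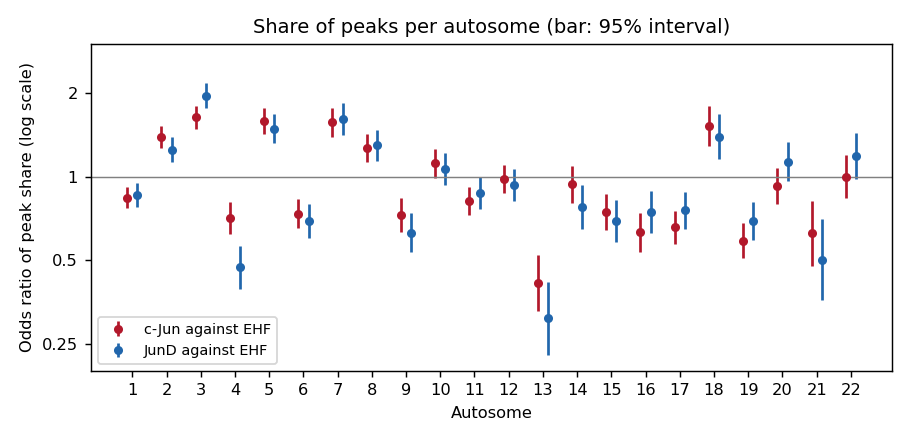
Odds ratio of the share of peaks on each autosome (y axis, log scale, grey line at 1) for c-Jun against EHF and JunD against EHF, with 95% intervals from counts as bars. Chromosome 3 stands highest, at 1.63 and 1.95, and chromosome 13 lowest, at 0.413 and 0.309.

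The densest EHF region of 100 kb was on chromosome 17 at 7123680 to 7218877, with 10 EHF peaks and 0 peaks of either Jun list. Of the 10 densest EHF regions, 4 were on chromosome 19, for example 39881906 to 39936377 with 9 EHF, 3 c-Jun and 3 JunD peaks. Together the 10 regions held 84 EHF peaks, 20 c-Jun peaks and 19 JunD peaks, and 3 of them had no c-Jun peak and 2 no JunD peak. The densest c-Jun region, on chromosome 14 at 101438968 to 101467836, held 12 c-Jun peaks, 4 JunD peaks and 0 EHF peaks. The next held 11 c-Jun peaks at 12956307 to 13055248 on chromosome 12. JunD was densest on chromosome 12 at 6387912 to 6482132, with 10 JunD and 8 c-Jun peaks, and 3 of its 10 densest regions were on chromosome 3. The densest c-Jun and JunD regions overlapped in 2 places, on chromosome 10 between 3797293 and 3867659 and on chromosome 6 between 30655263 and 30749856. None of the 10 EHF regions overlapped one of the Jun regions, a count of 0 that was not tested against chance.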

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

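The score strata, the lists without the top 5%, the loci of 1 kb and the alternatives for autosomes and windows were chosen after seeing the data. No paired analysis was possible because the deposited lists hold only the joint peaks of both replicates, so no replicate block could be fitted and no replicate could be left out. All 40 alternative values of the 5 overlaps stayed above chance with a permutation p of 0.001, and 69 of 74 alternatives in all kept their direction and side of the threshold or, for counts, lay within 1.5 times. The fold of EHF over both Jun lists ranged from 34.0 with peaks set to 200 bp to 72.6 with random placement, that of c-Jun over JunD from 197 to 720 and that of JunD over c-Jun from 196 to 721. The share of c-Jun peaks on a JunD peak was 52.7% with 200 bp peaks and 52.0% with an overlap of at least 50%, while the fold was 197 and 585, so the fold moved with the chance count. The overlapping share of EHF peaks fell from 11.1% to 7.72% in the better-scored 50% of the lists, where each list holds fewer peaks to meet, and the share that met any JunD peak fell from 7.09% to 4.57%. The EHF odds ratio of shared against c-Jun-only peaks fell to 1.11 over score strata and lost its call, while that of shared against JunD-only peaks gained one at 1.53 in the better-scored 50% and at 1.26 with 200 bp peaks, but at none of the other 6 alternatives, among them 1.07 (0.875 to 1.31) over score strata; the cause was not tested. Windows of 1 Mb in which JunD and EHF differed numbered 2 with all peaks, 6 in the better-scored 50% and 1 without the top 5% of peaks; the cause was not tested. For c-Jun against JunD, 0 of 2210 windows differed by Fisher's exact test with adjustment, and 2 had an unadjusted p below 0.05. The regions shared by these lists count on both sides of that test, so it can miss differences. The promoter, sequence pattern and gene list results and the placement matched on distance to genes were not run. Depth is unknown for every list, and differences in list length and lowest score limit any reading of sites found in 1 list only.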

Other observations

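The tests of windows, autosomes and the stretch of chromosome 17, and those over score strata and without the top 5% of peaks, were chosen only after the lists had been seen; for the score strata, the top 5% and the first test of the stretch the outcome each explanation needs was written down before its value was seen. Other stretches of the genome also differed between the lists. In the window of 174000001 to 175000000 on chromosome 3 there were 15 c-Jun peaks and 13 JunD peaks but 0 EHF peaks (Fisher's exact test, adjusted p = 0.0495 and 0.0145). On the same chromosome, the window of 170000001 to 171000000 held 19 JunD peaks and 4 EHF peaks (Fisher's exact test, adjusted p = 0.0483). EHF had more peaks than c-Jun at 30000001 to 31000000 on chromosome 16, with 19 EHF peaks and 0 c-Jun peaks (Fisher's exact test, adjusted p = 0.00462). The same held at 53000001 to 54000000 on chromosome 19, with 15 EHF peaks and 0 c-Jun peaks (Fisher's exact test, adjusted p = 0.0371). Against JunD, 0 windows were called as richer in EHF. All the windows named here were chosen by the test itself. Over 2454 windows of 1 Mb, the numbers of EHF peaks without a Jun peak and of c-Jun peaks without an EHF peak rose together (Pearson r 0.33, Spearman rho 0.34). For JunD in place of c-Jun, r was 0.37 and rho 0.38. For c-Jun-only and JunD-only peaks of the same cells, r was 0.28 and rho 0.27. All had a permutation p and an adjusted p of 1e-05, the smallest that 100000 resamples can give, and windows are not independent replicates.

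A first hypothesis is that the overlap of EHF with the Jun proteins comes from a few very high-signal regions found with any antibody, since regions on chromosome 21 between 9825454 and 9827536 were among the 10 best in all 3 lists. Without the top 5% of each list by score, EHF still met the Jun lists 38.3-fold over chance (35.7 to 41.2). The best of the 5 score groups held 306 of the 1259 EHF peaks on a Jun peak. For c-Jun it held 310 of the 1110 peaks on an EHF peak, and for JunD 192 of 803. Removing the top 5% could therefore not bring the overlap near chance, and its outcome is no separate evidence. These counts argue against a few best-scored regions as the source of most of the overlap. Regions of lower score found with any antibody were not tested. Nor do the counts say whether the best-scored regions themselves are binding sites. What stays open is that any pair of factors bound to open chromatin may overlap in this way, which no list of an unrelated factor was there to test.

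A second hypothesis is that EHF met regions of both Jun proteins more often than c-Jun-only regions because the former have the higher peak score. With c-Jun score strata held fixed, the odds ratio of 1.36 fell to 1.11 (0.960 to 1.28), which is consistent with that explanation. Whether a higher score reflects more open chromatin at these sites or stronger Jun binding was not tested.

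The third hypothesis concerns Calu-3 cells alone: extra DNA copies may raise Jun scores and peak numbers regionally. On chromosome 17, in the stretch of 37862148 to 38471117, the 2 c-Jun peaks outside the 10 best had a median score of 39 against 8 for as many consecutive peaks elsewhere (permutation p = 0.0004 over 10000 runs) and the 4 such JunD peaks 44 against 11 (permutation p = 0.0005), the outcome that extra copies need. Several of these peaks lie beside the peaks by which the stretch was chosen, so a narrower test was added after that result. Over 1 kb from every 10-best Jun peak there remained 1 c-Jun peak, with a score of 36 (permutation p = 0.0037), and 2 JunD peaks, with a median of 41 (permutation p = 0.0011), too few to decide. The 10 EHF peaks of the stretch, from HBE cells, had a median of 13.5 against 10.5 (permutation p = 0.0661), and the 8 over 1 kb from those Jun peaks had the same medians (permutation p = 0.0819). In the 609 kb after the stretch, 9 c-Jun peaks had a median of 30 against 7 for as many consecutive peaks elsewhere (permutation p = 0.0012) and 9 JunD peaks had 23 against 11 (permutation p = 0.0036), while 12 EHF peaks had 10.5 against 10.5 (permutation p = 0.572). The 609 kb before it held 0 c-Jun peaks and 1 JunD peak with a score of 8. Extra copies and a cluster of strong Jun sites both stay open, since factor and cell type change together and no measure of copy number was used here.

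The same explanation was also examined on whole autosomes, where 3 relations were computed. JunD scores had a Spearman rho of 0.28 (permutation p = 0.203, adjusted p = 0.2503) and a Pearson r of 0.40 (permutation p = 0.0656) with the ratio of c-Jun to EHF shares, and r was 0.18 without chromosomes 13 and 3. c-Jun scores had a rho of 0.71 (permutation p = 0.00038, adjusted p = 0.00114) and an r of 0.78 (permutation p = 1e-05) with the ratio of JunD to EHF shares, and r was 0.72 without these chromosomes. A JunD peak lay on 87.8% of the best c-Jun score group and 20.6% of the last. The c-Jun score and the JunD share are thus tied, and their relation cannot test copy number. A c-Jun peak likewise lay on 93.8% of the best JunD score group and 64.5% of the last. The JunD score and the c-Jun share are therefore tied as well, and their relation cannot test copy number either. EHF scores had a rho of -0.26 (permutation p = 0.2503) and an r of -0.18 (permutation p = 0.416) with the ratio of c-Jun to EHF shares, and r was -0.47 without these chromosomes. Since the Jun scores and Jun shares are tied and factor and cell type change together, copy number, cell type and factor cannot be told apart there. The window of chromosome 3 decided nothing, since it held 1 JunD-only peak, with a log2 score 0.53 above the median elsewhere (permutation p = 0.108).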
